A study of Mus musculus with 12 samples.

How the data were processed

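RNA was measured in 12 libraries of f10 mouse embryonic fibroblasts, per the labels. The cells are described as c-FOS knockout cells that express c-FOS again from a construct with a serum response element (SRE), a short control sequence that answers to serum. The construct holds wild-type c-FOS (here the WT line) or a SUMO-deficient c-FOS (here the SUMO-deficient line). Each line was uninfected or infected with Salmonella, giving 4 groups with 3 libraries each, numbered 1 to 3. Per the labels' protocols, cells were starved of serum for 16 h, infection ran for 4 h in antibiotic-free medium with 20% fetal bovine serum, and RNA was extracted with the RNeasy Mini kit after trypsin. The protocols do not say whether uninfected cells received serum after starvation, so infection and serum cannot be separated from the labels. Nothing says what a replicate number stands for, and p-values measure the spread between these libraries only.

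The authors deposited one table of raw counts per Ensembl gene for the 12 libraries; the values are whole numbers with no normalisation, as checked on the file. Per the submitters' processing notes, reads were made with bcl2fastq and the genome build was GRCm38. The aligner, the gene annotation, the counting tool, the read length, the library kit and whether counting used strand are not given in the sources used here. Without strand, reads of overlapping genes cannot be told apart: among the genes named in the report, Sp110, Cxcl11, Egfl7, Doc2g, Junb, Cebpd, Csf1r, Irf1, Fosl1, Mafg, Mafk, Vcl, Cdc20, Cdt1, Ccl2, Ppp1r15a, Sumo3 and Senp5 overlap another protein-coding gene in the annotation. Gene-level counts also cannot tell reads of a Fos construct from reads of an endogenous Fos transcript, and genes with near-identical copies elsewhere in the genome, such as Npm1, Tpi1 and the actin genes, are left out of the report because their reads could be split or dropped.

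The table holds 47643 genes, of which 28565 had 0 counts in all libraries. Symbols were found for 47224 identifiers; the other 419 held 0.0104% of the counts. Coordinates are from GENCODE M21 on GRCm38. Totals ranged from 4227499 to 7509581 counts per library and 13514 to 14798 genes were detected. Where a group had 0 counts, a fold was computed against a floor of 3 counts over the group, which was 0.162 CPM (counts scaled to a common library total) in the infected WT group; with 1 to 3 counts the ratio is given with its exact (Clopper-Pearson) 95% interval. Floors and intervals cover counting error only. Libraries of a group were compared pair by pair, and none was a copy of another: the smallest chi-square per gene between 2 libraries of a group was 3.40, over genes with at least 10 counts.

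Differences were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr left 10971 genes, TMM scaled the libraries, and a quasi-likelihood F test (robust, two-sided) was run on 4 group means with all 12 libraries in one model and no block. The 5 contrasts were infection in each line, the lines against each other without and with infection, and the interaction, which is the infection effect in the SUMO-deficient line minus that in the WT line. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and every adjusted p given for a gene is from this test unless another is named. Log2 fold changes are given with their standard error (SE), and CPM on TMM library sizes as mean and standard deviation (SD). The biological coefficient of variation was 0.257.

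Gene lists were tested with camera in limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The 26 lists covered AP-1 members, the SUMO machinery, immediate early genes of the serum response, cytoskeleton genes driven by SRF and MRTF, NF-kB feedback, cytokines and chemokines, interferon response, sensing of bacteria, genes linked to AP-1, extracellular matrix, S phase, G2 and M phase, ribosome biogenesis, sterol synthesis, ER and amino acid stress, starvation and quiescence, hypoxia and glycolysis, NRF2 targets, heat shock, p53 targets, TGF-beta response, fibroblast identity, and markers of myeloid, epithelial, endothelial and muscle cells. The last 4 had fewer than 5 measured members and were not tested as lists. With an estimated correlation in place of the preset one, no list passed in any contrast.

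The tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, for each contrast, the 8 genes with the largest rise and the 8 with the largest fall among those that pass, with CPM ranges that do not overlap and a mean of at least 5 CPM, up to 4 members of each list with the smallest adjusted p, any measured AP-1 or SUMO gene or marker of another cell type, and Fos. It leaves out, from the largest changes, symbols that are Gm with digits, end in Rik, hold -ps or lack a name, and asks nothing of CPM ranges for the interaction. The alternatives were RLE size factors, total counts only, DESeq2 1.42.0, limma-voom, no low-count filter, a filter on CPM of at least 1 in every library of a group, only the groups compared, the replicate number as a block, leaving out each library in turn, a threshold of 0.01, and an estimated correlation.

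After the values were seen, the libraries labelled WT uninfected replicate 3 and SUMO-deficient uninfected replicate 3 were doubted, because both carry transcripts that the other libraries hold in 1 line only. All results were therefore also computed without both, on 10 libraries and 11227 genes, where the coefficient of variation was 0.183. That choice was made after seeing the data. Where the comparison of the uninfected lines and the interaction had no gene past the threshold, the rule for naming genes was applied to the fit on 10 libraries. Some genes that the rule takes are not reported here.

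Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means across genes. Between the uninfected groups the correlations were 0.20, 0.43 and 0.42, all over 0.1. They do not show that the numbers pair those libraries. Deviations from a group mean are not independent, and a likeness of a single pair can raise all values. Both uninfected replicate 3 libraries correlated best with each other (r = 0.974 across genes). Deviations of libraries with different numbers were not compared, and the labels give no source for pairing. A fit with the number as a block also called 0 genes between the uninfected lines.

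The procedure was tested on simulated counts drawn from the real means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold. With 12 libraries edgeR recovered 28% and 84% of them for infection in the WT line, 28% and 81% in the SUMO-deficient line, 22% and 81% for the uninfected lines, 23% and 81% for the infected lines, and 7% and 57% for the interaction, over 10769 to 10798 genes. With 10 libraries these were 50% and 85%, 51% and 84%, 38% and 81%, 62% and 89%, and 20% and 71%. Unchanged genes called by edgeR numbered 2 to 9 per contrast with 12 libraries and 5 to 12 with 10. For infection in the SUMO-deficient line with 12 libraries, DESeq2 recovered 45% and 90% and called 20 unchanged genes. There edgeR called 4 and limma-voom 2. Each simulated data set was drawn only once. All simulated libraries of a group shared the same means, so none held transcripts of both lines as the uninfected replicate 3 libraries did. The percentages for 12 libraries therefore do not tell what share would be found in real comparisons with those libraries, such as the uninfected lines.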

Results

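RNA abundance was measured in mouse embryonic fibroblasts that lack their own c-FOS, a subunit of the transcription factor AP-1. They carry either wild-type c-FOS or a c-FOS that cannot be modified by SUMO. SUMO is a small protein attached to other proteins by a dedicated set of enzymes. Each line was left uninfected or infected for 4 h with Salmonella Typhimurium, a bacterium that invades host cells, and each of the 4 groups held 3 libraries. The series asks how AP-1 and the SUMO genes act on each other in infected cells. Library totals for replicates 1, 2 and 3 were 6500259, 5812658 and 5284939 counts in the uninfected WT line and 7376784, 7486836 and 4600052 in the infected WT line. They were 4227499, 5499435 and 4772593 in the uninfected and 4822986, 7509581 and 5636480 in the infected SUMO-deficient line. Transcripts of the mitochondrial genome took 1.08% ± 0.341 of the counts in uninfected and 2.25% ± 0.447 in infected WT libraries (SD, n = 3). In the SUMO-deficient line they took 1.20% ± 0.343 and 1.99% ± 0.123 (SD, n = 3). The 2 lines differ in the construct and in whatever else separates them, so a difference between lines cannot be assigned to the construct.

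Fos, the gene that was removed and put back (ENSMUSG00000021250, GRCm38 chromosome 12, 85473890 to 85477273), had counts in all 12 libraries and was lower in the SUMO-deficient line after infection. Its level was 174 ± 50.1 CPM in infected WT libraries and 24.1 ± 10.1 CPM in infected SUMO-deficient libraries (SD, n = 3), a log2 difference of -2.84 ± 0.65 (SE; adjusted p = 0.0464). All 3 infected SUMO-deficient libraries, at 25.3, 33.5 and 13.5 CPM, lay below the infected WT libraries, at 123, 174 and 223 CPM. Without infection the values were 96.9, 141 and 26.3 CPM in the WT line and 17.3, 7.72 and 33.1 CPM in the SUMO-deficient line. That difference of -2.19 ± 0.65 did not pass (adjusted p = 0.378). The log2 change of Fos with infection was 0.98 ± 0.60 in the WT line (adjusted p = 0.41) and 0.33 ± 0.64 in the SUMO-deficient line (adjusted p = 0.79), with neither passing. Reads of the construct and of any transcript left at the native locus cannot be told apart in these counts. The call among infected libraries was lost without WT uninfected replicate 1 (adjusted p = 0.0550), without SUMO-deficient uninfected replicate 1 (0.0689) and without any 1 of the 6 infected libraries (0.0777 to 0.161). Over all alternatives the adjusted p for Fos ranged from 0.00133 to 0.161.

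**Figure D1:**
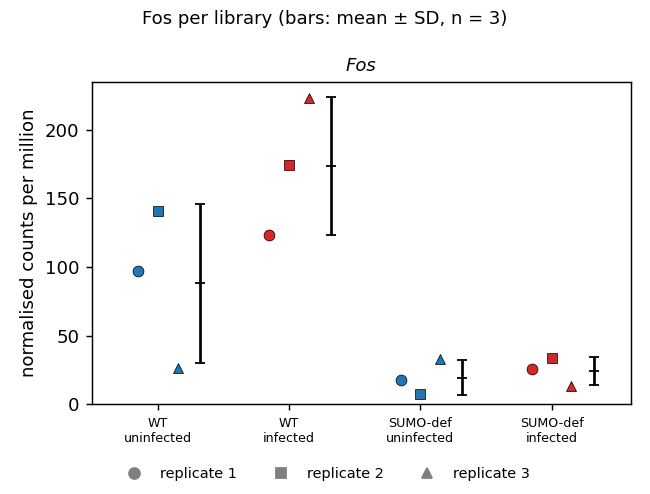
Fos in CPM for each of the 12 libraries by group, with bars at the mean and SD of 3 libraries. The infected WT libraries lie at 123 to 223 CPM and the infected SUMO-deficient libraries at 13.5 to 33.5 CPM, while both uninfected replicate 3 libraries lie near 30 CPM.

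Both libraries labelled uninfected replicate 3 carried transcripts of both lines. Among genes at least 4-fold apart between the lines in the other libraries, 8 were under 1 CPM in every other WT library, among them Tfap2b and Mageh1. All 8 were at 1 CPM or more in the library labelled WT uninfected replicate 3, where Tfap2b reached 7.96 CPM and Mageh1 12.4 CPM. Another 4, among them Tspan18 and Atp9a, were under 1 CPM in every other SUMO-deficient library. All 4 were at 1 CPM or more in SUMO-deficient uninfected replicate 3, where Atp9a reached 20.6 CPM. Over genes that changed at least 2-fold with infection in a fit without these 2 libraries, both also lay part of the way to the infected level of their line. The median share was 0.417 over 241 genes that rose and 0.457 over 280 that fell in WT uninfected replicate 3. In SUMO-deficient uninfected replicate 3 it was 0.417 over 382 and 0.523 over 381 genes (quartiles 0.0823 to 0.928 at the widest). Choosing genes without a library can draw its share upward, by an amount that was not measured. All fits were therefore also run without both libraries, a choice made after seeing the data, and part of the values below are given from that fit too.

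**Figure D2:**
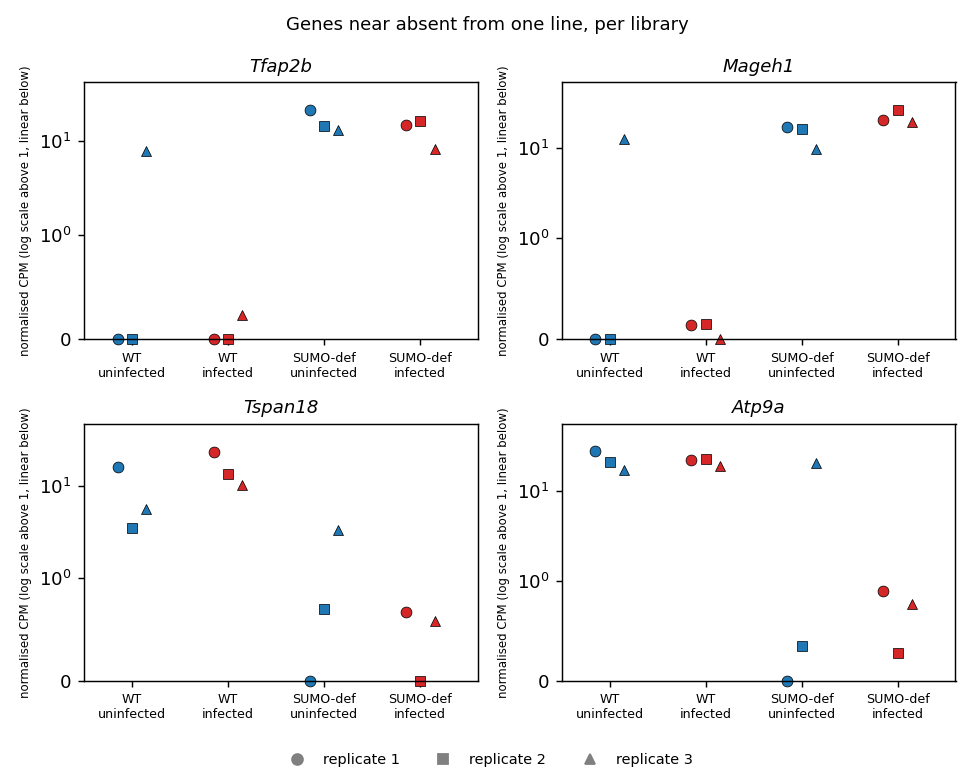
Tfap2b, Mageh1, Tspan18 and Atp9a in CPM for each library, on an axis that is logarithmic above 1 and linear below. Triangles mark replicate 3: in the library labelled WT uninfected replicate 3, Mageh1 is at 12.4 CPM, and in SUMO-deficient uninfected replicate 3, Atp9a is at 20.6 CPM.

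The first comparison asks what infection changed in cells with wild-type c-FOS. Socs3, which restrains cytokine signalling, rose by 2.93 ± 0.48 (log2, SE), from 327 ± 167 to 2491 ± 1162 CPM (SD, n = 3). The stress-induced transcription factor Atf3 rose by 1.86 ± 0.30, from 16.7 ± 9.03 to 60.2 ± 6.56 CPM. Cebpd, a transcription factor of the acute-phase response, rose by 2.16 ± 0.37, and Has1, which makes hyaluronan, by 2.73 ± 0.52. Crabp2, which carries retinoic acid, rose by 2.77 ± 0.62 and Rdh10, an enzyme of retinoic acid synthesis, by 2.26 ± 0.50. Also among the largest rises were the glycosyltransferase Gcnt2 at 1.88 ± 0.33, and Prag1 at 1.80 ± 0.28. Trib2, a pseudokinase, fell by 3.03 ± 0.38, from 48.3 ± 10.3 to 6.17 ± 3.87 CPM. Il34, a ligand of the CSF1 receptor, fell by 2.89 ± 0.53. Tab1, an adaptor of the kinase TAK1, changed by -2.61 ± 0.38, Jade2 by -2.37 ± 0.50, the R-spondin receptor Lgr6 by -2.34 ± 0.45, and Thap3 by -2.31 ± 0.40. For these genes all 3 infected libraries lay on the same side of all 3 uninfected ones, which the rule for naming them required.

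By group, the AP-1 genes and the immediate early genes were higher after infection in the WT line. Of 14 measured AP-1 members, 3 rose among all genes tested and 5 adjusted over the list alone: Atf3, Junb at 1.55 ± 0.25 (551 to 1612 CPM) and Jun at 0.78 ± 0.15 (110 to 189 CPM). The AP-1 list had a median of 0.62 (camera, adjusted p = 5.64e-07), with adjusted p = 0.208 with an estimated correlation. Of 24 immediate early genes 3 rose (9 adjusted over the list alone). Their median was 0.80 (adjusted p = 6.77e-10, and adjusted p = 0.208 with an estimated correlation). Dusp6, a phosphatase that restrains ERK, rose by 1.03 ± 0.21 (adjusted p = 0.0266), while Egr1 was at 1.00 ± 0.25 (0.0562). Of the other AP-1 members, Fosb was at 1.71 (adjusted p = 0.12), Fosl1 at 0.52 ± 0.20 (0.177), Fosl2 at 0.51 (0.28) and Mafk at 0.95 (0.10). Of 16 genes linked to AP-1 1 rose (4 up and 1 down adjusted over the list alone), with a list median of 0.43 (adjusted p = 0.000663, and adjusted p = 0.374 with an estimated correlation). It was Vegfa, a growth factor for blood vessels, at 1.5 ± 0.24, from 342 to 968 CPM.

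Inflammatory lists were higher as sets, while few of their members passed. Of the 20 cytokine and chemokine genes and the 19 NF-kB feedback genes 0 passed over all genes (5 and 4 rose adjusted over the list alone). Their medians were 0.73 (adjusted p = 0.000173) and 0.61 (adjusted p = 2.69e-05), each with adjusted p = 0.208 with an estimated correlation. Without both uninfected replicate 3 libraries 4 cytokine and chemokine genes rose and 1 fell over all genes, and 8 NF-kB feedback genes rose. With all libraries Lif, a cytokine of the interleukin 6 family, was at 3.44 ± 0.83 (adjusted p = 0.0667), and Il6 itself at 2.82 ± 0.71 (0.0715). The chemokine gene Ccl2 was at 1.44 ± 0.39 (0.0769) and Nfkbia, the inhibitor that NF-kB induces, at 0.87 ± 0.24 (0.0697). The interferon list had a median of -1.61, and 0 of its 24 members were above 0 (camera, adjusted p = 1.74e-08, and 0.437 with an estimated correlation). No member passed over all genes or over the list alone, with Cmpk2 at -4.14 ± 1.13 (adjusted p = 0.0882) and the antiviral gene Mx1 at -3.50 ± 1.01 (0.0967). Without both uninfected replicate 3 libraries the list median was -1.10, with 1 of 24 members above 0 (camera, adjusted p = 0.000614, and 0.643 with an estimated correlation).

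No change of the SUMO machinery with infection was detected in the WT line. None of its 23 measured members passed over all genes or over the list alone, and the median was 0.02 (camera, adjusted p = 0.583). The SUMO ligase genes Nsmce2 and Pias2 were at 0.57 and 0.46 (adjusted p = 0.17 and 0.15), and Senp2, a protease that removes SUMO, at 0.51 (0.16). Uba2, a subunit of the enzyme that activates SUMO, was at -0.48 (0.25). Without both uninfected replicate 3 libraries, Nsmce2 at 0.68, Uba2 at -0.66, Pias2 at 0.61 and Senp2 at 0.64 passed. Over all alternatives the lowest and highest adjusted p were 0.0144 and 0.439 for Nsmce2, 0.0180 and 0.600 for Uba2, 0.0191 and 0.435 for Pias2, and 0.0225 and 0.375 for Senp2.

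Among other groups in the WT line, 3 lists were higher after infection by camera. The hypoxia and glycolysis list had a median of 0.46 (0 of 16 rose, 3 adjusted over the list alone; adjusted p = 0.000173, and adjusted p = 0.208 with an estimated correlation). It had the glucose transporter gene Slc2a1 at 0.94 ± 0.26 (adjusted p = 0.0715). The heat shock list had a median of 0.31 (1 of 12 rose, 1 over the list alone; adjusted p = 0.00160, and adjusted p = 0.243 with an estimated correlation). The sterol list had a median of 0.40 (0 of 17, 2 over the list alone; adjusted p = 0.0286, and adjusted p = 0.620 with an estimated correlation). Without both uninfected replicate 3 libraries 9 of 16 hypoxia and glycolysis, 6 of 12 heat shock and 3 of 17 sterol genes rose over all genes. With all libraries Bag3, a co-chaperone, rose by 1.09 ± 0.22, Nop58, a ribosome biogenesis factor, by 0.94 ± 0.21, and Irs2, an insulin signalling adaptor, by 1.37 ± 0.25. Ppp1r15a, which reverses the block of translation under stress, rose by 1.57 ± 0.29, and the TGF-beta targets Bhlhe40 and Skil by 1.17 ± 0.27 and 0.75 ± 0.17. Plk1, a mitotic kinase, fell by 1.28 ± 0.28. The other 12 lists with a test did not pass. These were ribosome biogenesis (median 0.14, adjusted p = 0.121; 0.22 and 0.0441 without both uninfected replicate 3 libraries), TGF-beta response (0.08, 0.121), G2 and M phase (-0.42, 0.126), starvation (0.10, 0.247), NRF2 targets (0.10, 0.318), bacterial sensing (-0.05, 0.648), fibroblast identity (-0.15, 0.648), and p53 targets (0.14, 0.829). The signs of median, mean and test differed for S phase (median 0.06, mean -0.01, test up, adjusted p = 0.840), ER stress (-0.02, mean 0.003, test up, 0.840), SRF and MRTF targets (-0.03, mean 0.04, test up, 0.649), and matrix (0.05, mean and test down, 0.962). Marker lists of other cell types held 2 myeloid, 1 epithelial, 1 endothelial and 1 muscle gene, and none of these passed over all genes.

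Adjusted p of all genes named as risen or fallen in the WT line ran from 0.0145 (Atf3) to 0.0445 (Rdh10). With edgeR 241 of 10971 genes passed in the WT line, 89 higher and 152 lower, and 164 of them differed at least 2-fold. The balance moved with the alternatives: 797 higher and 567 lower without both uninfected replicate 3 libraries, 160 and 121 without WT uninfected replicate 3 alone, and 80 and 497 with total counts only. The count fell to 0 without WT infected replicate 1 or 2 (1455 and 1441 genes at an unadjusted p under 0.05, against 2133 with all libraries). It was 3 without WT uninfected replicate 1 (Trib2, Junb and, chosen after its values were seen, Khdc4). It was 89 without WT uninfected replicate 2, and 95, 89 and 145 without SUMO-deficient infected replicates 1, 2 and 3. Those SUMO-deficient libraries are not compared in this contrast, but they enter the filter, the scaling and the spread. The count rose to 791 without SUMO-deficient uninfected replicate 3 and to 1364 without both uninfected replicate 3 libraries. In the latter fit 87 of the 89 and 151 of the 152 genes passed again.

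Lif, Ptgs2 and Cxcl1 were among the genes that rose with infection in the SUMO-deficient line. Lif rose by 3.97 ± 0.86 (log2, SE), from 17.3 ± 16.0 to 274 ± 102 CPM (SD, n = 3). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose by 3.29 ± 0.63 (239 to 2336 CPM) and the neutrophil chemokine gene Cxcl1 by 2.83 ± 0.75 (400 to 2842 CPM). Bdkrb1, an inducible bradykinin receptor, rose by 3.05 ± 0.62, Socs3 by 2.23 ± 0.47, Sat1, an enzyme of polyamine breakdown, by 2.21 ± 0.44, Prag1 by 2.07 ± 0.28 and Rab11fip1 by 2.05 ± 0.36. Atoh8, a transcription factor, fell by 3.27 ± 0.44, from 184 to 19.0 CPM, and Mlycd, which breaks down malonyl-CoA, changed by -2.98 ± 0.42. Klhdc8a changed by -2.59 ± 0.48 and Rnf135, a ubiquitin ligase of RNA sensing, by -2.54 ± 0.33. The adjusted p of Lif, Ptgs2, Cxcl1 and Socs3 were 0.0268, 0.0174, 0.0484 and 0.0210 with all libraries and 0.0565, 0.0501, 0.0758 and 0.0550 without both uninfected replicate 3 libraries. Over all alternatives they were 9.79e-05 to 0.0972, 3.83e-08 to 0.137, 0.00169 to 0.157 and 1.85e-08 to 0.0750.

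The AP-1 and immediate early lists were also higher after infection in the SUMO-deficient line. Of 14 AP-1 members 4 rose (6 adjusted over the list alone): Atf3 at 1.75 ± 0.30, Junb at 1.32 ± 0.25, Fosl1 at 1.06 ± 0.21 and Mafg at 0.79 ± 0.21. The list median was 0.26 (camera, adjusted p = 0.00167, and adjusted p = 0.307 with an estimated correlation). Over the alternatives run for lists this median ranged from 0.26 to 0.68. Jun was at 0.03 ± 0.15 (adjusted p = 0.924), Fosb at 1.68 (0.095) and Fosl2 at 0.84 (0.053). Of 24 immediate early genes 5 rose (13 adjusted over the list alone), with a median of 0.82 (adjusted p = 2.63e-08, and adjusted p = 0.307 with an estimated correlation). Among them were Dusp6 at 1.72 ± 0.21 (99.1 to 326 CPM), the transcription factor gene Egr1 at 1.31 ± 0.25, Phlda1 at 1.38 ± 0.35 and the survival gene Mcl1 at 0.58 ± 0.15. Of 16 genes linked to AP-1 5 rose (6 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.000375, and adjusted p = 0.355 with an estimated correlation). They included Vegfa at 1.38 ± 0.24, Cd44, a hyaluronan receptor, at 0.82 ± 0.20, and Spp1, a secreted matrix protein, at 1.21 ± 0.31. Over the same alternatives the median of the genes linked to AP-1 ranged from 0.40 to 0.73.

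Of 23 SUMO genes measured in the SUMO-deficient line, 1 passed over all genes, and 1 rose and 2 fell adjusted over the list alone. Nsmce2, the SUMO ligase of the SMC5/6 complex, rose by 1.08 ± 0.22 (49.7 to 105 CPM, adjusted p = 0.0152, and 0.000178 to 0.132 over all alternatives). Uba2 was at -0.72 (adjusted p = 0.063). The SUMO proteases Senp7 and Senp5 were at -1.27 (0.092) and 0.54 (0.23). The list had a median of -0.09, while the test pointed up (camera, adjusted p = 0.911). On 10 libraries, without both uninfected replicate 3 libraries, 2 of 24 SUMO genes rose and 2 fell (median 0.15, adjusted p = 0.704).

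Cytokine genes had a median of 1.07 in the SUMO-deficient line (2 of 20 rose, 6 adjusted over the list alone; adjusted p = 0.000196, and adjusted p = 0.307 with an estimated correlation). NF-kB feedback genes had a median of 0.53 (1 of 19 rose and 1 fell, 5 and 1 over the list alone; adjusted p = 0.000466, and adjusted p = 0.307 with an estimated correlation). Sod2, the mitochondrial superoxide dismutase, rose by 1.07 ± 0.19 and Irf1, a transcription factor of the interferon system, fell by 1.49 ± 0.31. The interferon list had a median of -0.47, with 7 of 24 members above 0, and did not pass (adjusted p = 0.341). It passed without both uninfected replicate 3 libraries (median -0.69, adjusted p = 0.03, and 0.804 with an estimated correlation; 0 of 24 members passed). Of 15 bacterial sensing genes 1 rose, Casp4, the caspase that binds bacterial lipopolysaccharide, by 1.20 ± 0.31. The list had a median of -0.21 and a test pointing up (adjusted p = 0.862).

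Metabolic and growth lists were higher after infection in the SUMO-deficient line. Of 16 hypoxia and glycolysis genes 3 rose (6 adjusted over the list alone; median 0.61, adjusted p = 0.000151, and adjusted p = 0.307 with an estimated correlation). Among them were Slc2a1 at 1.43 ± 0.26 and Ndrg1 at 1.25 ± 0.35. Of 17 sterol genes 2 rose (7 adjusted over the list alone; median 0.62, adjusted p = 0.000247, and adjusted p = 0.401 with an estimated correlation). Among them was the sterol carrier gene Stard4 at 1.10 ± 0.19. Of 18 ribosome biogenesis genes 7 rose (7 over the list alone; median 0.34, adjusted p = 0.00124, and adjusted p = 0.467 with an estimated correlation). Among them were Nop58 at 1.04 ± 0.22, the rRNA methyltransferase gene Fbl at 0.79 ± 0.18 and Ncl, encoding nucleolin, at 0.80 ± 0.19. Of 12 heat shock genes 2 rose (3 over the list alone; median 0.44, adjusted p = 0.00254, and adjusted p = 0.307 with an estimated correlation), namely Hspa4 at 0.77 ± 0.16 and Bag3 at 1.00 ± 0.23. The G2 and M list was lower (median -0.67; 1 of 14 fell, 1 over the list alone; adjusted p = 0.0129, and adjusted p = 0.401 with an estimated correlation). Cdc20, which activates the anaphase-promoting complex, fell by 1.10 ± 0.21.

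Single members changed in other groups of the SUMO-deficient line. Id1, a BMP and TGF-beta target, fell by 1.24 ± 0.22 and Bhlhe40 rose by 1.13 ± 0.27. Col6a1, a collagen chain of the matrix list, changed by -0.72 ± 0.14, Pik3ip1 by -1.87 ± 0.37, Trib2 by -1.40 ± 0.34, and Csf1r, a myeloid marker, by -1.34 ± 0.29. Lists that did not pass were NRF2 targets (median 0.25, adjusted p = 0.146), SRF and MRTF targets (-0.22, 0.409), matrix (-0.16, 0.569), fibroblast identity (0.08, 0.778), TGF-beta response (-0.10, 0.862) and p53 targets (-0.06, 0.867). The signs of median and test differed for S phase (median -0.05, mean 0.08, test up, adjusted p = 0.778), starvation (median 0.14, mean -0.16, test up, 0.778) and ER stress (median -0.05, test up, 0.862), which did not pass either.

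Adjusted p of the genes named as risen or fallen in the SUMO-deficient line ran from 0.00456 (Dusp6) to 0.0484 (Cxcl1). With edgeR 850 genes passed in the SUMO-deficient line, 409 higher and 441 lower, with 428 at least 2-fold. The balance moved with the alternatives: 267 higher and 1101 lower with total counts only, 475 and 401 with RLE, 486 and 377 with limma-voom, and 1133 and 821 without both uninfected replicate 3 libraries. With only the 2 groups compared 209 passed. The count fell to 69, 126 and 141 without SUMO-deficient infected replicates 1, 2 and 3, to 295 without SUMO-deficient uninfected replicate 1, and to 549 and 517 without WT infected replicates 1 and 2. It rose to 1297 without SUMO-deficient uninfected replicate 3. Without both uninfected replicate 3 libraries it was 1954. Of the genes tested in both fits, 396 of 409 and 389 of 440 passed again.

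Whether the 2 lines answered infection alike was asked across genes and by the interaction. Of the genes that passed, 61 were higher in both lines, where 3.32 would be expected from the counts alone, and 106 were lower in both (6.11 expected). Atf3, Junb, Socs3, Dusp6, Mcl1, Vegfa, Bag3 and Nop58 were among those higher and Trib2 among those lower. None passed in opposite directions, and 99.6% of the genes that passed in the WT line had the same sign in the other. Log2 fold changes correlated across the 10971 tested genes (Pearson 0.609, Spearman 0.669), and genes are not independent replicates. Without both uninfected replicate 3 libraries the shared numbers were 573 higher and 293 lower. They were 0 and 0 without WT infected replicate 1 or 2, where the WT line had no calls. No gene passed the interaction in edgeR (305 at an unadjusted p under 0.05) or in limma-voom (312) or DESeq2 (327). The interaction was -0.75 ± 0.22 for Jun and -0.65 ± 0.88 for Fos (adjusted p = 1.0 each). For Fos its sign is not settled, since it was 0.42 without both uninfected replicate 3 libraries and ran from -1.16 to 0.92 over all alternatives. A gene that passed in 1 line alone was thus not shown to differ between lines. Among lists, interferon genes had a median interaction of 1.45 with 22 of 24 members above 0 (camera, adjusted p = 4.72e-09, and adjusted p = 0.718 with an estimated correlation). It was 0.55 without both uninfected replicate 3 libraries (adjusted p = 0.179). There the lists of genes linked to AP-1 (0.23, 0.0376), G2 and M (-0.45, 0.0188) and starvation (-0.28, 0.0316) passed, as did 3 lists that also passed with all libraries (adjusted p = 0.0392 each). These 3 were ribosome biogenesis (0.20, 0.00494), sterol synthesis (0.33, 0.00494) and TGF-beta response (-0.23, 0.0222). None of the 6 passed with an estimated correlation. The SUMO list had a median of 0.02 with a test pointing down (adjusted p = 0.507) and the AP-1 list -0.27 (0.261).

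**Figure D3:**
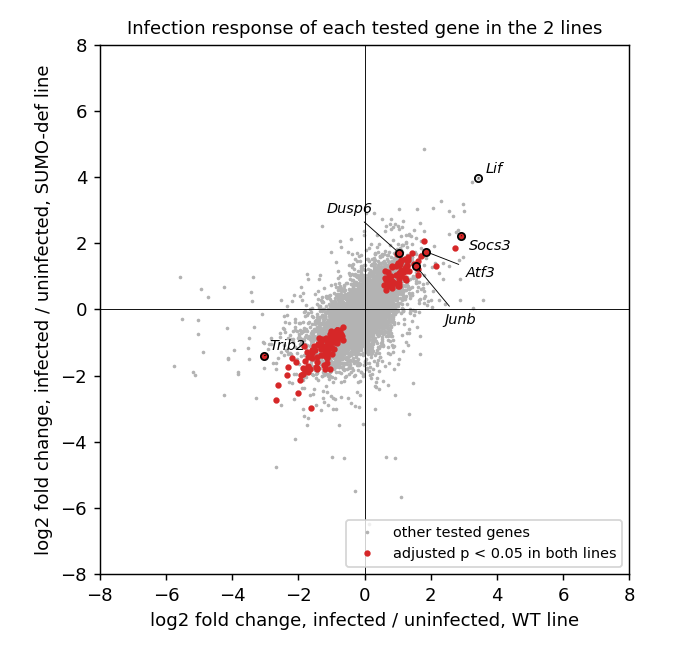
Log2 fold change with infection in the WT line (horizontal) against that in the SUMO-deficient line (vertical) for each tested gene, with genes that passed in both lines in red. The 61 genes higher in both, such as Socs3 and Atf3, lie in the upper right and the 106 genes lower in both, such as Trib2, in the lower left.

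Among infected libraries, the interferon list was higher and the list of SRF and MRTF targets lower in the SUMO-deficient line by camera, where 2 of 24 and 3 of 19 members passed over all genes. With an estimated correlation neither list passed (adjusted p = 0.275 and 0.296). All 24 measured interferon genes were above 0, with a median of 2.85. Of these 2 passed over all genes and 21 adjusted over the list alone (camera, adjusted p = 4.90e-25, and adjusted p = 0.275 with an estimated correlation). Stat2, a transcription factor of the interferon pathway, was higher by 2.14 ± 0.42 (log2, SE), 9.74 ± 5.12 against 41.9 ± 2.48 CPM (SD, n = 3). Cmpk2, a nucleotide kinase induced by interferon, was higher by 4.78 ± 1.11. Mx1 was at 3.93 (adjusted p = 0.061). The interferon genes were uneven among infected WT libraries: Stat2 was at 6.86, 6.71 and 15.7 CPM and Cmpk2 at 0.140, 0.143 and 2.07 CPM in replicates 1, 2 and 3. In the infected SUMO-deficient line they were at 44.5, 41.7 and 39.5 CPM and 14.1, 18.2 and 21.2 CPM. Of 15 bacterial sensing genes 0 passed over all genes and 4 rose adjusted over the list alone (median 0.55, adjusted p = 0.00707, and adjusted p = 0.275 with an estimated correlation). Tlr3, a sensor of double-stranded RNA, was at 3.09 ± 0.75 (0.0513) and Nod1, a sensor of bacterial cell walls, at 1.01 ± 0.28 (0.0662).

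**Figure D4:**
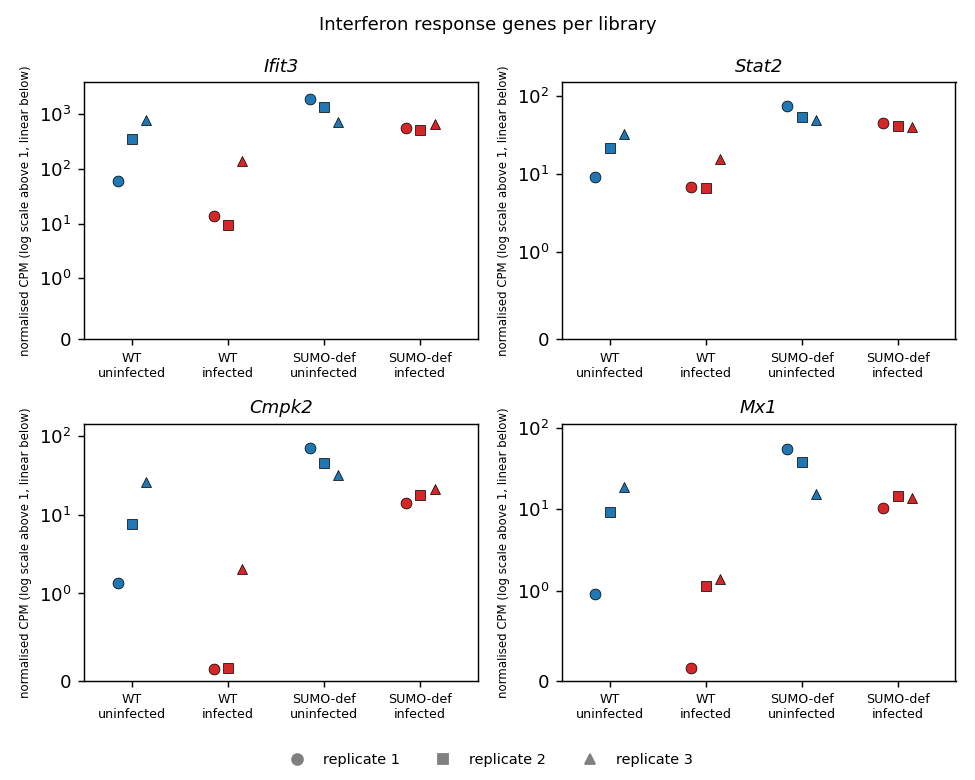
Ifit3, Stat2, Cmpk2 and Mx1 in CPM for each library, on an axis that is logarithmic above 1 and linear below; Ifit3 was chosen after its values were seen. Stat2 lies at 6.71 to 15.7 CPM in infected WT libraries and at 39.5 to 44.5 CPM in infected SUMO-deficient libraries.

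Cxcl11, a chemokine gene that interferon induces, was higher in the infected SUMO-deficient line by 4.86 ± 0.75 and Slfn8 by 4.71 ± 1.05. Sp110, a nuclear body gene, had 81 counts against 0 over 3 libraries each, at least 29.8-fold higher against a floor of 3 counts over the group. Rspo3, an activator of Wnt signalling, was higher by 4.70 ± 1.02, Apod, a lipid carrier, by 4.27 ± 0.88 (7.29 against 138 CPM) and Syt7 by 4.88 ± 1.13. Tfap2b, a transcription factor (chromosome 1, 19208914 to 19238576), had 227 counts against 1 (ratio 250, exact 95% interval for counting error 44.5 to 9933). Lower were Tspan18 by -5.33 ± 1.05, Egfl7, an endothelial marker, by -4.06 ± 0.95, Cpeb1 by -3.98 ± 0.86 and Nkain4 by -3.81 ± 0.66. So were the secreted Wnt regulator Sfrp1 by -3.53 ± 0.68, Smoc2 by -3.24 ± 0.66, and Doc2g, with 3 counts against 144 (ratio of the WT to the SUMO-deficient line 43.5, interval 14.6 to 213.5).

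Of 19 SRF and MRTF targets 3 were lower in the infected SUMO-deficient line (8 adjusted over the list alone; median -0.62, adjusted p = 4.28e-06, and adjusted p = 0.296 with an estimated correlation). Myl9, a myosin light chain (chromosome 2, 156775420 to 156781658), was at 24.5 ± 5.2 against 129 ± 8.95 CPM (-2.40 ± 0.52). The focal adhesion gene Vcl was lower by -1.03 ± 0.20. Mmp9, a matrix protease (22.7 against 154 CPM, -2.76 ± 0.61), was lower among the 16 genes linked to AP-1. Spp1 was higher by 1.68 ± 0.31 (1 up and 2 down, 1 and 3 over the list alone; adjusted p = 0.158). Of 20 matrix genes 2 were lower (2 up and 3 down over the list alone; adjusted p = 0.169). These were the collagen gene Col3a1 at -1.23 ± 0.24 and Postn, which encodes periostin, at -2.09 ± 0.42 (373 against 87.6 CPM). Twist2, a mesenchymal transcription factor of the fibroblast list, was higher at 480 ± 46.8 against 176 ± 20.4 CPM (1.45 ± 0.19, adjusted p = 0.0110). The keratin gene Krt19, an epithelial marker, was lower by -2.31 ± 0.37, and Plk1 was higher by 1.17 ± 0.28. Gclm, a subunit of the enzyme that makes glutathione, and the small heat shock gene Hspb1 were lower by -0.91 ± 0.20 and -0.66 ± 0.15.

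Within the AP-1 list Fos alone passed among infected libraries (1 up and 2 down adjusted over the list alone; median -0.40, adjusted p = 0.168), with Jun at -0.59 ± 0.15 (adjusted p = 0.053) and Mafk at -0.66 (0.25). None of the 23 SUMO genes passed over all genes or over the list alone (median -0.11, adjusted p = 0.362). The cytokine list had 4 up and 1 down adjusted over the list alone and 0 over all genes (median 0.24, adjusted p = 0.168), and the immediate early list had none of either (median -0.43, 0.0913). For NF-kB feedback the median was 0.05 with the mean and test pointing down (adjusted p = 0.786).

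Adjusted p of the genes named as higher or lower between the infected lines ran from 0.0110 (Twist2) to 0.0483 (Cmpk2). With edgeR 342 genes passed between the infected lines, 181 higher and 161 lower in the SUMO-deficient line, 269 of them at least 2-fold. The count was 0 without any 1 of WT infected replicates 1 and 2 and SUMO-deficient infected replicates 1 and 2 (1468 to 1527 genes at an unadjusted p under 0.05, against 2017). It was 36 without SUMO-deficient infected replicate 3, and 543 and 809 without the uninfected replicate 3 library of the WT and of the SUMO-deficient line. Without both of these it was 1355, with 181 of 181 and 160 of 161 passing again. There 6 of 24 interferon genes were higher and 6 of 19 SRF and MRTF targets lower, and the hypoxia and glycolysis list also passed (median 0.30, adjusted p = 0.0365, and 0.443 with an estimated correlation).

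Between the uninfected lines no gene passed with all 12 libraries in edgeR (1023 at an unadjusted p under 0.05), none passed in limma-voom (1158) and 52 passed in DESeq2. As sets, interferon genes were higher in the SUMO-deficient line (median 1.49, 24 of 24 above 0; camera, adjusted p = 9.03e-17), as were G2 and M genes (0.36, 0.00492) and bacterial sensing genes (0.18, 0.00943). Lower were SRF and MRTF targets (-0.39, adjusted p = 0.000182), genes linked to AP-1 (-0.31, 0.00143), immediate early genes (-0.36, 0.00385) and ribosome biogenesis genes (-0.10, 0.0440). None held with an estimated correlation, at adjusted p = 0.668 for ribosome, 0.582 for immediate early and 0.430 for the other lists. Adjusted over the list alone, 4 genes linked to AP-1, 2 immediate early genes and 1 ribosome gene were lower. SUMO genes had a median of -0.08 (adjusted p = 0.722).

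Without both uninfected replicate 3 libraries, 756 genes passed between the uninfected lines, 380 higher and 376 lower in the SUMO-deficient line. Leaving out the WT library alone gave 197 and the SUMO-deficient library alone 208. Mmp9 was lower by -3.22 ± 0.27 (SE), Myl9 by -2.44 ± 0.19, Postn by -2.06 ± 0.38 and Fos by -3.25 ± 0.54. With all libraries these values were -1.76, -1.20, -1.64 and -2.19. Stat2 was higher by 2.08 ± 0.42, Tlr3 by 3.63 ± 0.41, the bacterial lipoprotein receptor gene Tlr2 by 2.36 ± 0.39 and Il33, a cytokine of the interleukin 1 family, by 4.62 ± 0.52. With all libraries Stat2, Tlr3 and Il33 were at 1.5, 2.04 and 1.35. Over all alternatives Tlr2 ran from 0.73 to 2.38, with adjusted p of 0.000154 to 0.999. Adjusted p over all alternatives was 6.78e-07 to 0.999 for Mmp9, 0.00276 to 0.999 for Stat2 and 0.00218 to 0.999 for Fos. Tbx10, a T-box transcription factor (chromosome 19, 3992752 to 3999512; 2006 counts in the WT line against 0), was at least 529-fold lower. With all libraries Tbx10 was at -1.72 ± 1.39 (adjusted p = 0.772, and 3.69e-07 to 0.999 over all alternatives), and Adcyap1r1, a neuropeptide receptor, at -2.67 ± 1.05 (0.491). Tfap2b and Mageh1 were then at 2.71 ± 1.05 (0.483) and 1.83 ± 1.10 (0.662).

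Of 19 SRF and MRTF targets 6 were lower on 10 libraries (7 adjusted over the list alone; median -0.61, adjusted p = 5.63e-07, and adjusted p = 0.410 with an estimated correlation). Of 24 interferon genes 3 were higher (4 over the list alone; median 2.19, adjusted p = 2.47e-15, and adjusted p = 0.410 with an estimated correlation), with Cmpk2 at 3.75 ± 0.74 and Mx1 at 3.25 ± 0.75. In the matrix list 1 was higher and 4 lower (1 and 5 over the list alone), including Col3a1 at -0.83 ± 0.18 and Postn. Itga5, the fibronectin receptor subunit, was lower by -1.67 ± 0.26, and Cdt1, which licenses replication, by -1.44 ± 0.25. Cdkn1b, a cell cycle inhibitor, was higher by 1.05 ± 0.19, as was Bnip3, a hypoxia target, by 1.29 ± 0.22. With all libraries Cmpk2, Mx1, Col3a1, Itga5, Cdt1, Cdkn1b and Bnip3 were at 2.11, 1.92, -0.54, -1.12, -0.85, 0.47 and 0.81, and none passed. Lists that passed here alone were cytokines (median 0.70, adjusted p = 0.0450), starvation (0.36, 0.0453), hypoxia and glycolysis (0.33, 0.0118) and, lower, p53 targets (-0.72, 0.0340). With an estimated correlation they did not pass (0.406 to 0.564). Of 24 SUMO genes 1 was higher and 1 lower (1 and 1 over the list alone; median -0.16, adjusted p = 0.269). Sumo3 was lower by -0.45 ± 0.13, but at -0.12 ± 0.20 with all libraries (adjusted p = 0.916). Over all alternatives it ran from -0.45 to 0.04, with adjusted p of 0.0399 to 0.999. Genes that passed between the lines in both states numbered 270 higher and 242 lower, where 22.8 would be expected each. Twist2 (0.67 ± 0.15), Krt19 (-1.59 ± 0.32), Mmp9 and Myl9 were among them in the uninfected cells and in the infected ones. With all libraries Twist2 and Krt19 were at 0.36 and -0.95 in the uninfected cells.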

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

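The lists below were picked because camera found their infection effect to differ between the lines; the fit without both uninfected replicate 3 libraries was chosen only after results were seen, as was the removal of trends from the difference in infection effects, and the other tests named here were written before.

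Interferon response genes differed most by camera at the preset correlation. Their estimated correlation was 0.866, and with estimated correlations TGF-beta response genes had the lowest adjusted p (camera, 0.378). No interferon gene passed the interaction over all genes or over the list alone. The median of the infection effect in the SUMO-deficient line minus that in the WT line was 1.45 over 24 members (adjusted p = 4.72e-09, and 0.718 with an estimated correlation), with medians of -1.61 in the WT line and -0.47 in the SUMO-deficient line. On differences of mean log2 CPM, a measure other than the fitted fold changes that gave 1.45 and 2.85, the difference in infection effects was 1.53 before and 1.53 after smooth trends in gene length and GC content were removed, and the list lay 3.32 above the WT line among infected libraries before and 3.32 after, which argues against such a trend as the cause. Reads of the SUMO-deficient line in WT infected replicate 3 could add to the uneven WT values: over 77 line genes outside the list that library lay at a median share of 0.0900 of the way to the SUMO-deficient level (quartiles 0 and 0.226), against -0.0172 and -0.00676 in WT infected replicates 1 and 2. The zero level for each library was the mean of the other infected WT libraries, so replicate 3 is part of it for replicates 1 and 2. That alone can push the shares of replicates 1 and 2 below 0, whatever sets replicate 3 apart. Choosing genes without a library can also draw its share upward. A share of 0.1 or more would have spoken for such reads and one under 0.05 against them, so that explanation stays open. In WT infected replicate 3, 21 interferon genes had a median share of 0.252. That library also correlated better with WT uninfected replicate 2 (r = 0.971 across genes) than with WT infected replicates 1 and 2 (0.963 and 0.968). Whether it answered infection less than those replicates was not tested. An effect of the construct or of the line stays open as well and cannot be separated by this design, and without both uninfected replicate 3 libraries the median interaction was 0.55 (adjusted p = 0.179).

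Sterol synthesis genes had a median difference of 0.27 over 17 members (adjusted p = 0.0392, and 0.718 with an estimated correlation), with 0.40 in the WT and 0.62 in the SUMO-deficient line. Ribosome biogenesis genes had a median difference of 0.15 over 18 members (adjusted p = 0.0392, and 0.718 with an estimated correlation), with 0.14 and 0.34. On 10 libraries, without both uninfected replicate 3 libraries, the sterol and ribosome differences were 0.33 and 0.20 (adjusted p = 0.00494 each) and with the replicate number as a block 0.27 and 0.19, with neither passing. TGF-beta response genes had a median difference of -0.19 over 15 members (adjusted p = 0.0392, and 0.378 with an estimated correlation), with 0.08 and -0.10; on 10 libraries it was -0.23 (0.0222) and with the block -0.18, not passing.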

How the results depend on the processing

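The alternatives without the replicate 3 libraries, and those that join 2 choices, were chosen after seeing the data. Counts below are genes changed, with those higher and lower in parentheses, and the cause of each change in count was not tested except where named.

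RLE size factors, limma-voom and the filter on CPM of at least 1 in every library of a group gave counts within 1.5 times those reported (230 to 281 in the WT line, 863 to 876 in the SUMO-deficient line, 339 to 445 between the infected lines, 0 between the uninfected lines and for the interaction); that filter kept more genes, 11119, than the 10971 of filterByExpr. DESeq2 gave 698 (321 and 377) for the WT line, 1397 (741 and 656) for the SUMO-deficient line, 52 (19 and 33) for the uninfected lines and 771 (407 and 364) for the infected lines. On simulated counts for infection in the SUMO-deficient line, DESeq2 called 20 unchanged genes where edgeR called 4. With no low-count filter, on 19078 genes, the counts were 460 (187 and 273) for the WT line, 51 (19 and 32) for the uninfected and 531 (264 and 267) for the infected lines. Total counts only moved the median log2 fold change of all genes to -0.19 in the WT and -0.24 in the SUMO-deficient line, from -0.03 and -0.05, and gave 577 (80 and 497) and 1368 (267 and 1101), so 13.9% against 36.9% and 19.5% against 48.1% of the changed genes were higher. With only the 2 groups compared, the counts were 103 (49 and 54), 209 (132 and 77) and, for the infected lines, 1598 (789 and 809). At an adjusted p under 0.01, 0 (0 and 0), 45 (29 and 16) and, for the infected lines, 0 (0 and 0) passed.

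With the replicate number as a block the counts were 169 (70 and 99) for the WT line and 756 for the SUMO-deficient line. They were 0 for the uninfected lines (1001 at an unadjusted p under 0.05) and 161 (88 and 73) for the infected lines. Deviations of same-numbered libraries correlated at -0.22 to 0.07 for infection in the WT line and -0.10 to 0.01 in the SUMO-deficient line. Between the infected lines they correlated at 0.03 to 0.14, and none of these values shows pairing. With the block and only the 2 groups compared, 0 (0 and 0) genes changed in either line with infection (1675 and 1952 at an unadjusted p under 0.05) and 2011 (1001 and 1010) between the infected lines. Without both uninfected replicate 3 libraries, the block gave 1941 (1083 and 858), 2311 (1321 and 990), 1098 (531 and 567) for the uninfected and 1710 (840 and 870) for the infected lines, and 1 (0 and 1) for the interaction, Socs3 at -1.26 ± 0.19 (adjusted p = 0.0318).

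Without both uninfected replicate 3 libraries and no block the counts were 1364 (797 and 567), 1954 (1133 and 821), 756 (380 and 376) and 1355 (674 and 681), and 0 for the interaction (562 at an unadjusted p under 0.05); with only the 2 groups compared as well, they were 755 (440 and 315), 2282 (1279 and 1003), 195 (108 and 87) and 1598 (789 and 809). Without all 4 replicate 3 libraries they were 1997 (1025 and 972), 1725 (1008 and 717), 1030 (542 and 488), 1241 (651 and 590) and, for the interaction, 11 (5 and 6).

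Leaving out each library in turn gave 0 to 791 genes changed in the WT line (0 to 360 higher, 0 to 431 lower), 69 to 1297 in the SUMO-deficient line (42 to 737, 27 to 560), 0 to 208 between the uninfected lines (0 to 138, 0 to 141), 0 to 809 between the infected lines (0 to 396, 0 to 413) and 0 for the interaction. The log2 change of Fos ranged from 0.58 to 1.49 with infection in the WT line and from -0.06 to 0.97 in the SUMO-deficient line, its difference from -2.83 to -1.68 between the uninfected and from -3.16 to -2.55 between the infected lines, and its interaction from -1.16 to -0.01. That interaction was 0.42 without both uninfected replicate 3 libraries, 0.38 there with the block and 0.92 without all 4 replicate 3 libraries, so its sign is not stable. The correlation of the infection responses ranged from 0.499 to 0.614, with 0 to 241 genes higher and 0 to 201 lower in both lines.

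For Fos between the infected lines, the call was lost with no filter (-2.84, adjusted p = 0.0950), with the block (-2.87, 0.0951) and with the block and only the 2 groups compared (-2.85, 0.0567). Between the uninfected lines Fos passed without both replicate 3 libraries (-3.25, 0.0139), there with only the 2 groups compared (-3.24, 0.0173) and without all 4 (-3.25, 0.00218). The correlation of the infection responses was 0.664 without both, with 573 genes higher and 293 lower in both lines, and 0.696 over genes with a mean of at least 5 CPM.

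Of 165 values of named genes, none changed sign between all libraries and an alternative where it passed in either of the 2. Values that did not pass with all libraries did change sign: Jun with infection in the SUMO-deficient line ran from -0.17 to 0.12, Sumo3 between the uninfected lines from -0.45 to 0.04, and Fos with infection in the SUMO-deficient line from -0.06 to 1.28. The call or its absence was kept for 162 with RLE, 154 with total counts only (6 lost, 5 gained), 142 with DESeq2 (1 lost, 22 gained), 154 with limma-voom (5 and 6), 134 with no filter (19 and 12), 139 with the block (22 and 4) and 112 without both uninfected replicate 3 libraries (7 and 46), and for 121 of 160 with only the 2 groups compared (33 and 6). With the block and only the 2 groups compared, 82 of 160 were kept, with 72 lost and 6 gained. Without single libraries the number kept ran from 90 (SUMO-deficient infected replicate 1, 75 lost) to 150 (WT infected replicate 3, 15 lost), and 63, 64, 67 and 63 were lost without WT infected replicates 1 and 2 and SUMO-deficient infected replicates 2 and 3. Of 110 list tests, 77 were kept with an estimated correlation and 33 lost, and without both uninfected replicate 3 libraries 99 were kept, 1 lost and 10 gained. With the block 107 were kept and 3 lost, the interactions of ribosome biogenesis, sterol synthesis and TGF-beta response. A depth of 4227499 to 7509581 counts limits genes of few counts, and changes of 2-fold were recovered less often than 4-fold changes in simulated data.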

Other observations

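The tests of a label swap, of mixed libraries and of serum, and the fits without the replicate 3 libraries, were chosen only after the results were seen; the tests of length and GC content and the splits were planned.

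Without all 4 replicate 3 libraries, 11 genes passed the interaction. Tbx3 at 1.79 ± 0.23, Sema4b at 1.85 ± 0.30, Nr2f2 at 1.32 ± 0.21, Soga1 at 1.39 ± 0.23 and Grem1, a BMP antagonist, at 1.68 ± 0.21 had a higher infection effect in the SUMO-deficient line (log2, SE). Stat5a at -1.82 ± 0.27, the aggrecan-cleaving protease gene Adamts4 at -2.14 ± 0.32, the mTOR inhibitor gene Ddit4 at -1.73 ± 0.27, Rnf122 at -2.71 ± 0.43, Socs3 at -1.35 ± 0.22 and Cebpd at -1.70 ± 0.19 had a lower one. Adjusted p ran from 0.00527 (Cebpd) to 0.0383 (Socs3) in that fit, while with all 12 libraries no gene passed; for Socs3 adjusted p ranged from 0.0318 to 1.0 over all alternatives.

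The uninfected replicate 3 libraries of both lines lay between the lines. Over 102 line genes the median share of the SUMO-deficient level was 0.489 (quartiles 0.341 and 0.648) in the library labelled WT and 0.474 (0.274 and 0.695) in the one labelled SUMO-deficient. A swap of labels between 2 unmixed libraries would need shares near 1 and 0, which 0.489 and 0.474 argue against. If both libraries hold both lines, the shares cannot tell which label belongs to which, so a swap of such libraries stays open. A trend in length or GC content is argued against by 0.499 after its removal. Mixed RNA or reads of both lines may explain the values: the share from genes higher in the SUMO-deficient line and the share from genes higher in the WT line differed by at most 0.0719. A mixture predicts equal shares, and a difference of up to 0.2 was allowed, a limit set after the values were seen. Likeness of these medians is weak evidence, since the shares of single genes spread widely, as the quartiles show. Both libraries also lay at 0.417 to 0.523 of the way to the infected level of their line by median. The share that a mixture of the 2 uninfected lines would give was not computed. Choosing genes without a library can also draw its share upward. What else these libraries hold, if anything, therefore stays open. The mixture is a hypothesis found and tested on the same data, and no biological explanation was tested.

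The infection response shared by the lines had a correlation across genes of 0.675 before and 0.667 after removal of length and GC trends (on differences of mean log2 CPM, a measure other than the fitted fold changes that gave 0.609), which argues against such a trend as its cause. Serum given with the bacteria could account for part of it, since the labels do not say whether uninfected cells received serum; the NF-kB feedback list, with a median of 0.611 in the WT line, decides nothing because serum and infection are confounded. An effect of Salmonella itself stays open too and cannot be told apart from serum for these genes.

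Other splits of the same libraries were counted. For infection in the WT line 1 of 10 splits, the real one, gave as many genes (241 real, 71 in the highest other). For the SUMO-deficient line it was 1 of 10 (850 real, 0 in the highest other) and for the infected lines 1 of 10 (342 real, 0). For the uninfected lines all 10 of 10 gave as many as the real 0, which any split does, and the highest other split, which groups WT uninfected replicates 1 and 2 with SUMO-deficient uninfected replicate 1, gave 2; the splits that part all replicate numbers gave 0. With 10 splits no share under 0.05 can be had. For the interaction 50 of 50 splits drawn out of 200 gave as many as the real 0. Any split must when the real count is 0, so this says nothing about chance. The highest other split gave 458. It kept the infected WT libraries apart from the infected SUMO-deficient ones, and set SUMO-deficient uninfected replicates 1 and 2 with the infected WT libraries. The difference between the infected lines thus enters its count. That split also put both uninfected replicate 3 libraries on the same side. Other splits that did so gave 0, among them a split that also kept the infected lines apart. That placement alone therefore does not account for the count.

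WT uninfected replicate 3 correlated best with SUMO-deficient uninfected replicate 3 (r = 0.974 across genes). WT infected replicate 3 correlated best with WT uninfected replicate 2 (0.971), above its values with WT infected replicates 1 and 2 (0.963 and 0.968). Transcripts of the mitochondrial genome took 1.738% of its counts, against 2.474% and 2.545% in WT infected replicates 1 and 2. The split of the WT libraries with 71 genes changed set it with WT uninfected replicates 2 and 3.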
